A study of Rattus norvegicus with 9 samples.

How the data were processed

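RNA was measured in 9 rat back skin samples, 3 untreated, 3 with imiquimod and 3 with imiquimod and epidural lidocaine, and groups were taken from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol from frozen, ground skin and libraries followed standard Illumina protocols. The submitters' processing notes name bcl2fastq, STAR 2.5.3a and DESeq2. The counting tool, genome build, annotation, strand setting and rule by which genes were selected are not given in the sources used here. The labels do not state that each sample is a separate animal, so limma p-values measure the spread between these samples.

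The authors deposited 2 tables with gene ID, symbol and, per library, log2(normalized count + 1), of 6025 and 399 rows. The imiquimod libraries have the same values in both tables (largest difference 4.97e-09), so all 9 libraries share 1 scaling. The smallest difference of group means was 1.0 on the log2 scale in both tables, so a minimum difference of 1 is visible in the rows. After removal of the log, all values corresponding to at most 2000 reads were whole multiples of a step per library within 0.01, which gave the reads and the size of 1 read, 0.817 to 1.24 normalized counts. Depth is known only for listed genes. Where a group had 0 reads in all libraries, a fold is given as a lower bound against 3 reads per library, which covers counting error only, since the reads carry no molecular identifiers in the sources used here.

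Differences were tested on the deposited log2 values with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with python 3.11.15, numpy 2.4.6 and pandas 2.3.3 for tables and statsmodels 0.14.6 for adjustments over lists. Each table was tested alone, without a block, with Benjamini-Hochberg adjustment over the rows of the table and a threshold of 0.05. Fold changes on the log2(normalized count + 1) scale understate those of low genes. Because the rows were chosen on the same libraries, adjusted p-values are too small. In simulated tables with no difference, 158 of 6025 genes were kept by a difference of 1 and an unadjusted p under 0.05, and 119 of them were called when tested only among themselves. For 399 genes it was 14 of 14. Neither the scaling nor the genes that were not listed could be rechecked.

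The test was tested on simulated data with 200 changed genes per table. At the 6025 rows it called 8.96%, 58.2% and 69.7% of genes changed by 2-fold, 4-fold and 8-fold and 0.137% of unchanged genes. At the 399 rows it called 20.9%, 74.6% and 84.8%, and 2.51% of unchanged genes. These rates depend on the share of changed genes, so they are not comparable between the 2 tables. They also do not carry over to the real tables, where 5287 and 128 rows passed. Replicates of a group were compared by chi-square over genes, and each pair differed by far more than sampling noise (chi-square per degree of freedom 130 to 713).

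Before the data were examined, 31 gene lists with 630 genes were fixed (364 and 28 of these are in the imiquimod and the lidocaine table), covering the IL-23/IL-17 axis, antimicrobial and interferon genes, epidermis, hair, sebaceous gland, leukocyte types, vessels, nerve, muscle, fat, pigment and stress. For each list with at least 5 members past the threshold, the split of higher and lower was compared with that of all other genes past it (Fisher's exact test, two-sided, scipy 1.17.1), adjusted over the 24 lists so tested in the imiquimod comparison. Of these, 17 had an adjusted p under 0.05. Counts given as adjusted over the list alone use only the members listed in that table. Those members were selected on the same libraries, so such counts are no independent check. The named genes were fixed by rule at the same time as the lists. They are, per comparison and direction, the 8 largest differences and the 4 smallest adjusted p among genes past the threshold with a mean of at least 100 normalized counts and a gene symbol. Added are up to 4 members per list with the smallest adjusted p and a panel of 20 psoriasis and nerve genes wherever listed. For genes past the threshold in both tables, the 8 per sign pattern with the smallest adjusted p were taken. Clone names, dashes and date-like symbols were not taken as symbols. Other list members that are named were chosen after their values were seen.

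Gene symbols are those of the tables. A RefSeq gene table of assembly GRCr8 held 5058 of the 6025 and 310 of the 399 symbols, and was used only for its number of protein-coding genes, 23154. No coordinates are given, since the tables hold none. Symbols altered to dates (8 rows) were left as they stand. Genes with near-identical copies or overlapping models are uncertain, because the handling of shared reads is not given in the sources used here.

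Alternatives covered a stricter threshold, a minimum difference, a minimum mean of 100 or 1, symbols only, a Bonferroni threshold, a pseudocount of 0.1, a replicate block and leaving out each library. Added after seeing the data were voom on the recovered reads, an adjustment as if all 23154 protein-coding genes had been tested, and, for genes in both tables, all listed genes and leaving out each library. Count models were planned only for deposited counts and were not run on the recovered reads.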

Results

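RNA was sequenced from 9 back skin samples of Sprague Dawley rats of 250 g, in 3 groups of 3 samples. The untreated rats received nothing. The imiquimod rats had imiquimod, a Toll-like receptor 7 agonist used to induce psoriasis-like inflammation, on the back skin for 6 days. The lidocaine rats had the same 6 days of imiquimod and, from day 3, an epidural injection of 1% lidocaine, a local anaesthetic that blocks voltage-gated sodium channels, for 4 days. Skin was collected on day 7. No group with a vehicle in place of imiquimod, and none with a sham epidural injection, is among the labelled groups. Effects of a vehicle or of handling therefore cannot be told apart from those of imiquimod. The 2 tables analysed hold only genes that passed a selection by the authors, 6025 gene IDs for imiquimod against untreated skin and 399 for imiquimod with lidocaine against imiquimod. A gene absent from a table is therefore not listed, which does not mean unchanged. Reads on the listed genes came to between 15947423 and 22929894 per library in the imiquimod table and between 417714 and 803921 in the lidocaine table. The total depth of the libraries is unknown. Values are given as normalized read counts (mean ± SD, n = 3 samples) or as differences of group means on the log2(normalized count + 1) scale with the standard error (SE) and the limma adjusted p.

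The comparison of imiquimod with untreated skin asks how the transcriptome of skin given imiquimod for 6 days differed from that of untreated skin. The listed changes were led by interferon-induced and immune cell genes on the higher side and by genes of the hair follicle and sebaceous gland on the lower side. Of the 6025 listed genes, 5287 passed an adjusted p of 0.05 in limma, 2831 higher and 2456 lower with imiquimod. Of these, 1706 of the higher and 1117 of the lower genes differed by more than 4-fold. Groups did not overlap for 86.7% of the listed genes, where chance gives 10% for 3 libraries against 3 in genes that were not, as these were, selected on the same libraries. Tlr7 (ENSRNOG00000004249), which encodes the receptor of imiquimod, rose from 260.2 ± 123 to 10352 ± 1656 normalized counts (log2 difference 5.40 ± 0.41 SE, limma adjusted p = 0.00021).

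Genes of the type I interferon response rose together. All 29 of its listed members were higher and past the threshold, of 30 in the list (Fisher's exact test, two-sided, of higher against lower among genes past the threshold, adjusted p = 2.37e-07; 29 also when adjusted over the list alone). Fisher p-values here and below take genes of the same libraries as units, so they describe splits across genes, not the spread between samples. Oasl, an interferon-induced antiviral gene, rose from 75.39 ± 14.96 to 18594 ± 2403 normalized counts (log2 difference 7.94 ± 0.28 SE). The ubiquitin-like modifier gene Isg15 rose by 7.09 ± 0.26, the transcription factor gene Irf7 by 6.54 ± 0.27 and the antiviral GTPase gene Mx2 by 6.86 ± 0.31 on the same scale. Among the largest differences in the table were Ifit1bl (11.75 ± 1.21 SE) and the guanylate-binding protein gene Gbp1 (11.20 ± 1.17 SE), whose untreated levels were 5.74 ± 9.95 and 3.04 ± 5.27 normalized counts.

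Chemokine and cytokine genes were mostly higher. Of 22 listed chemokines 20 rose and 2, Ccl22 and Ccl27, fell (Fisher's exact test adjusted p = 0.00098; 22 past the threshold when adjusted over the list alone). Cxcl10 and Cxcl11, ligands of the T cell chemokine receptor CXCR3, rose by 10.10 ± 0.37 and 9.64 ± 0.35 on the log2 scale. The monocyte chemokine genes Ccl7 and Ccl12 rose by 5.71 ± 0.31 and 10.63 ± 0.96. Cxcl3 was at 0 reads in the untreated rats and at 870.2 ± 406 normalized counts after imiquimod, at least 272-fold higher against a floor of 3 reads per library. In the list of inflammatory cytokines and NF-kB or STAT3 feedback genes 21 of 22 listed members rose and none fell (Fisher's exact test adjusted p = 1.63e-05; 21 adjusted over the list alone). Il6 and Il10 were at 0 reads in the untreated rats and at least 118-fold and 76.4-fold higher after imiquimod. Il1b rose from 359.9 ± 141 to 2813 ± 646 normalized counts, and the prostaglandin synthase gene Ptgs2 rose by 3.29 ± 0.28 on the log2 scale.

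In the list of the IL-23/IL-17 axis and IL-20 family, the cytokine pathway of psoriasis, 12 of 18 listed members rose, 3 fell and 3 did not pass, a split that did not differ from other changed genes (Fisher's exact test adjusted p = 0.083; 15 past the threshold when adjusted over the list alone). The epidermal cytokine genes Il36g and Il36a rose from 835.3 ± 200 to 15534 ± 4610 and from 54.7 ± 5.84 to 1056 ± 504 normalized counts. Il24 rose by 4.75 ± 0.35 and the chemokine gene Ccl20 by 1.96 ± 0.30 on the log2 scale. Il12b, which encodes the p40 subunit of IL-12 and IL-23, was at 0 reads without imiquimod and at least 9.70-fold higher with it. Il23a, for the other subunit of IL-23, fell from 78.9 ± 6.24 to 38.7 ± 22.6 normalized counts (limma adjusted p = 0.041), and Il20 also fell. The IL-17 genes lay near the detection limit. Il17a had 0 reads in every untreated library and 8, 0 and 9 reads in the imiquimod libraries (adjusted p = 0.058). Il17f had 0, 3 and 39 reads after imiquimod (adjusted p = 0.099), and Il22 had 1, 2 and 16 (adjusted p = 0.035). The call of Il22 was lost without untreated replicate 1, 2 or 3 or imiquimod replicate 2, and that of Il23a in 5 of the 6 runs that left out 1 library, all but imiquimod replicate 2, with limma adjusted p up to 0.082 and 0.118. Without imiquimod replicate 2 Il17a passed (limma adjusted p = 0.00156), and without imiquimod replicate 1 Il17f did (0.0194). Without imiquimod replicate 3 the log2 difference of Il17f moved from 2.35 to 1.01 and that of Il22 from 2.11 to 1.25.

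Antimicrobial peptide and alarmin genes rose in 8 of 9 listed members and fell in 1, which was not beyond the split among other genes (Fisher's exact test adjusted p = 0.058; 9 adjusted over the list alone). The neutrophil and keratinocyte alarmin genes S100a8 and S100a9 rose from 2065 ± 547 to 34812 ± 8738 and from 1205 ± 326 to 55321 ± 12518 normalized counts, the protease inhibitor gene Slpi by 4.98 ± 0.29 and the siderophore-binding gene Lcn2 by 1.88 ± 0.35 on the log2 scale. The beta-defensin genes Defb52 and Defb4 were at 0 reads in the untreated rats and were at least 1442-fold and 310-fold higher after imiquimod.

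Markers of leukocytes rose list by list. Whether cells entered the skin or resident cells raised these genes was not tested. Macrophage and monocyte markers rose in 18 of 18 listed members (Fisher's exact test adjusted p = 6.6e-05), with Adgre1, the F4/80 gene, up by 4.16 ± 0.33, Cd300lf by 7.43 ± 0.34 and the high-affinity IgG receptor gene Fcgr1a by 5.25 ± 0.34. T and NK cell markers rose in 24 of 25 and fell in 1, the transcription factor gene Gata3 (adjusted p = 3.32e-05). Cd8a rose from 21.8 ± 12.6 to 12177 ± 2749 normalized counts, the perforin gene Prf1 by 6.05 ± 0.33, Klrk1 by 7.04 ± 0.42 and the granzyme gene Gzmb by 10.41 ± 0.85. Neutrophil markers rose in 12 of 15 and fell in 1 (adjusted p = 0.0086), among them the G-CSF receptor gene Csf3r at 6.53 ± 0.35 and Itgb2 at 4.43 ± 0.42. Dendritic and Langerhans cell markers rose in 21 of 22 listed gene IDs (adjusted p = 0.00014), including Ccr7, which directs dendritic cell migration, at 6.76 ± 0.32, Itgax at 5.92 ± 0.57 and Clec9a at 3.31 ± 0.39. The exception was Cd207, which encodes langerin of Langerhans cells and fell from 614.6 ± 236 to 136.1 ± 129 normalized counts (limma adjusted p = 0.028), a call lost without untreated replicate 1 or 3 or imiquimod replicate 3 (adjusted p up to 0.081). Its log2 difference moved from -2.68 to -1.76 without imiquimod replicate 2. All members past the threshold in these 4 lists also passed when adjusted over the list alone, at 18, 25, 13 and 22. Of B and plasma cell markers 5 of 6 rose and of mast cell markers 5 of 8, neither split differing from other genes (adjusted p = 0.26 and 0.76; 6 and 8 adjusted over the list alone).

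Endothelial and vascular activation genes rose in 10 of 10 listed members (Fisher's exact test adjusted p = 0.0064; 10 adjusted over the list alone). The leukocyte adhesion genes Sele, Selp and Icam1 rose by 2.86 ± 0.39, 2.68 ± 0.41 and 2.16 ± 0.25 on the log2 scale. Matrix proteases and inhibitors rose in 12 of 14 and fell in 1 (adjusted p = 0.0086; 13 adjusted over the list alone), with the collagenase gene Mmp13 at 7.39 ± 0.61 and Timp1 at 2.93 ± 0.25. The macrophage elastase gene Mmp12 was at 0 reads in untreated skin and at least 721-fold higher after imiquimod. Further large rises were those of the itaconate synthase gene Acod1, at least 707-fold higher from 0 reads, and the hexokinase gene Hk3 (11.13 ± 0.73 SE). Klra5 and Ly49i2, NK cell receptor genes of the Ly49 family, were at least 289-fold and 254-fold higher from 0 reads, and are uncertain as single genes because near-identical copies exist in this family.

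**Figure D1:**
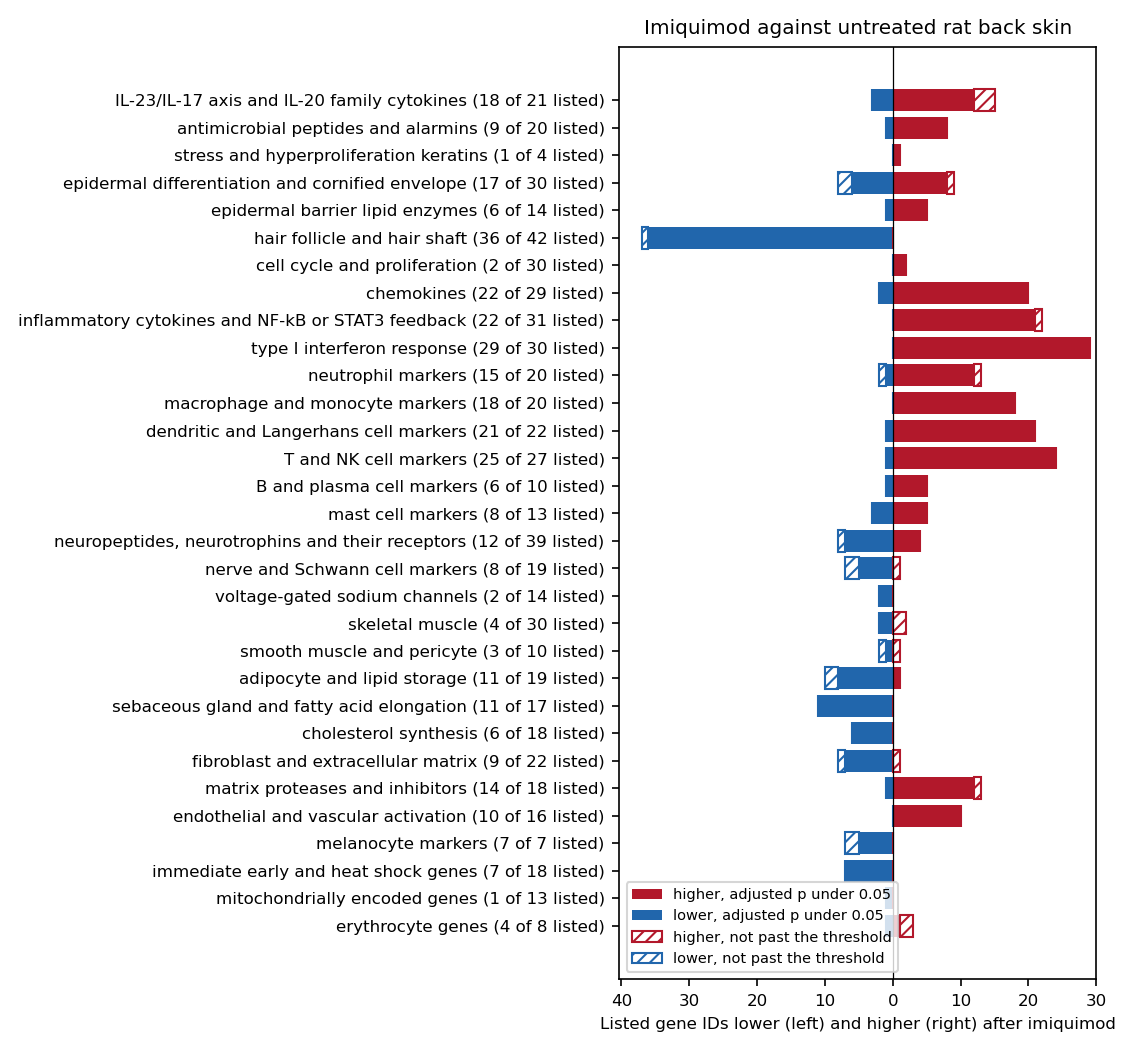
Listed members of each fixed gene list that were lower (left) or higher (right) after imiquimod than in untreated rat back skin, counted as gene IDs, with filled bars for an adjusted p under 0.05 in limma and hatched bars for those not past it. The type I interferon list has 29 members higher and the hair list 36 gene IDs lower past the threshold.

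Epidermal genes moved in both directions. In the list of differentiation and cornified envelope genes 8 of 17 listed members rose, 6 fell and 3 did not pass (Fisher's exact test adjusted p = 1.0; 14 adjusted over the list alone). The envelope genes Sprr2d and Rptn rose from 38.9 ± 9.08 to 4570 ± 654 and from 155.8 ± 21.7 to 9994 ± 1401 normalized counts. The involucrin gene Ivl fell from 6379 ± 1309 to 472.5 ± 191, Crct1 fell from 17885 ± 3045 to 3806 ± 77.2, and the keratin gene Krt77 had a log2 difference of -11.64 ± 1.499 SE. Il1f10 (IL-38) fell from 2349 ± 654 to 65.6 ± 11.7 normalized counts. Krt16, a keratin of activated and hyperproliferating epidermis, rose by 5.05 ± 0.45 (limma adjusted p = 0.00032) and was the listed member of the 4 stress keratins. Of the 30 cell cycle genes, Rrm2 (2.44 ± 0.35 SE) and Tyms (1.79 ± 0.27 SE), both of nucleotide synthesis, were listed, and both rose. Of the epidermal barrier lipid enzymes 5 of 6 rose, among them the glucosylceramide synthase gene Ugcg at 1.86 ± 0.26, and Abhd5 fell by 1.09 ± 0.24 (Fisher's exact test adjusted p = 0.26; 6 adjusted over the list alone).

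Genes of the hair follicle and hair shaft were lower in all 37 listed gene IDs, 36 of them past the threshold (Fisher's exact test adjusted p = 2.15e-11; 36 adjusted over the list alone), with a median log2 difference of -7.55. That median was -5.24 without imiquimod replicate 2 and -9.54 without imiquimod replicate 3. The inner root sheath keratin gene Krt72 had a difference of -9.25 ± 1.83 SE and the companion layer keratin gene Krt75 of -3.81 ± 0.61, and the follicle regulators Msx2, Foxn1 and Lef1 fell by 4.99 ± 0.78, 3.38 ± 0.60 and 3.21 ± 0.45. The hair list took 19.8%, 23.3% and 13.4% of the listed reads in untreated replicates 1, 2 and 3, and 0.387%, 0.0259% and 2.20% in imiquimod replicates 1, 2 and 3. Sebaceous gland and fatty acid elongation genes fell in 11 of 11 listed members (adjusted p = 0.00074; 11 adjusted over the list alone). These included the wax ester synthase genes Awat1 (-9.34 ± 1.24 SE) and Awat2 (-6.42 ± 0.54 SE) and the desaturase gene Scd (-4.06 ± 0.39 SE). Cholesterol synthesis genes fell in 6 of 6 (adjusted p = 0.017; 6 adjusted over the list alone), with Insig1 at -3.16 ± 0.31. Among genes with a symbol and a mean of at least 100, Lao1 had the largest decrease (-12.18 ± 0.83 SE), followed by Krt77 and the keratin-associated protein gene Krtap31-1 (-10.36 ± 1.80 SE). Aadacl4, Cyp2b12, Tm4sf4, Fcgbp and Hapln4 fell by 9.16 ± 0.80, 8.90 ± 0.64, 8.84 ± 1.38, 7.65 ± 0.39 and 6.69 ± 0.39. Chga, a secretory granule gene of neuroendocrine cells, was at 335.1 ± 34.7 normalized counts in untreated skin and at 0 reads after imiquimod, at least 124-fold lower.

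Listed genes of other resident tissues were mostly lower, except endothelial genes, of which 10 of 10 listed were higher. Of the matrix, adipocyte, nerve and skeletal muscle lists, 13 of 22, 8 of 19, 11 of 19 and 26 of 30 members were not listed. The direction of those members is unknown. The medians of the lists below were less far down than those of the hair (-7.55) and sebaceous (-4.06) lists on the log2 scale. Fibroblast and extracellular matrix genes fell in 7 of 9 listed members (Fisher's exact test adjusted p = 0.0086; 7 adjusted over the list alone), with the collagen genes Col1a1 and Col3a1 down by 2.99 ± 0.36 and 2.40 ± 0.39 on the log2 scale. Adipocyte genes fell in 8 of 11 and Pparg rose (adjusted p = 0.024; 9 adjusted over the list alone), and the adiponectin gene Adipoq fell from 10742 ± 4642 to 2387 ± 1005 normalized counts. Melanocyte markers fell in 5 of 7 listed members (adjusted p = 0.03; 5 adjusted over the list alone), with the melanin synthesis gene Dct at -3.93 ± 0.99. The calls of 2 of the 5 were lost without untreated replicate 1 or imiquimod replicate 2 or 3, those of Mlana and Pmel, and that of Mlana also without untreated replicate 3 (limma adjusted p up to 0.0639). Nerve and Schwann cell markers fell in 5 of 8 (adjusted p = 0.03; 5 adjusted over the list alone), with S100b at -2.01 ± 0.38 and the myelin gene Mag at -4.84 ± 1.00. Immediate early and heat shock genes fell in 7 of 7 (adjusted p = 0.0086; 7 adjusted over the list alone), with Egr2 at -2.18 ± 0.44 and Hspb1 at -1.69 ± 0.31. Of the neuropeptide, neurotrophin and receptor genes 4 rose and 7 fell of 12 listed (adjusted p = 0.4; 11 adjusted over the list alone), with the galanin receptor gene Galr2 down by 2.01 ± 0.31 and the BDNF receptor gene Ntrk2 by 1.49 ± 0.32. The sodium channel genes Scn8a and Scn10a both fell, the second from 25, 3 and 20 reads to 2, 0 and 0. The remaining lists had under 5 members past the threshold and no test. Here 2 of 4 skeletal muscle genes, 1 of 3 smooth muscle genes and 1 mitochondrially encoded gene (Mt-nd3) fell, and of 4 erythrocyte genes Hbe1 rose and Slc4a1 fell. Adjusted over the list alone, the counts were 1, 1, 1 and 2. The skeletal muscle gene Casq1 lost its call without untreated replicate 1 or 3 or imiquimod replicate 1 or 3 (limma adjusted p up to 0.0953). The call of Mt-nd3 was lost without untreated replicate 1 or 2 or imiquimod replicate 2 (limma adjusted p up to 0.0789), and that of Slc4a1 without untreated replicate 1 or 2 (up to 0.0599).

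These p-values come from limma, adjusted by Benjamini-Hochberg over the listed genes, and are too small because the authors chose the genes on the same libraries. When the adjustment was made as if 23154 protein-coding genes had been tested, 3733 genes passed. Of the 157 called named genes, 19 lost their call, among them Cd207, Il22 and Il23a (limma adjusted p = 0.107, 0.135 and 0.158).

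The comparison of imiquimod plus epidural lidocaine with imiquimod alone asks what the injections changed in inflamed skin. The listed differences were fewer and mostly downward, 131 higher and 268 lower. Of the 399 genes 128 passed an adjusted p of 0.05 in limma, 44 higher and 84 lower. Involucrin (Ivl, ENSRNOG00000009314), a cornified envelope protein gene, fell further, from 472.5 ± 191 to 108.4 ± 20.8 normalized counts (log2 difference -2.06 ± 0.49 SE, limma adjusted p = 0.019). The chloride channel regulator gene Clca5 (ENSRNOG00000013334) fell from 1778 ± 1247 to 225.3 ± 11.01 (adjusted p = 0.019). Ptx3 (ENSRNOG00000012280), which encodes a soluble pattern recognition protein, rose from 366.6 ± 202 to 2128 ± 1645 normalized counts (2.39 ± 0.73 SE, adjusted p = 0.038). The epoxide hydrolase gene Ephx2 rose from 47.6 ± 20.9 to 235.5 ± 109 (2.25 ± 0.58 SE, adjusted p = 0.024). The call of Ivl was lost without imiquimod replicate 1 (adjusted p = 0.0655). Clca5 and Ephx2 kept theirs in 2 of 6 runs that left out 1 library, and Ptx3 in 1 of 6, without lidocaine replicate 3.

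With a symbol and a mean of at least 100 normalized counts, the higher genes past the threshold were Ptx3, Ephx2 and the pseudogene Psme1-ps1 (1.53 ± 0.44 SE), whose reads may not be separable from those of its parent gene. The lower genes with the largest differences were Palm3 (-3.94 ± 1.32 SE), Clca5 (-2.65 ± 0.64 SE), Fam210a (-2.30 ± 0.66 SE), the cell cycle inhibitor gene Cdkn2b (-2.12 ± 0.64 SE), the potassium channel gene Kcna2 (-2.12 ± 0.71 SE), Ivl, the serpin gene Serpina12 (-2.05 ± 0.70 SE) and the serine protease gene Tmprss11g (-1.98 ± 0.68 SE). Skint8, of a family of epidermal and thymic membrane proteins, was among those with the smallest adjusted p (-1.95 ± 0.58 SE, adjusted p = 0.036). Without lidocaine replicate 3 the difference of Palm3 came to -2.03 and that of Tmprss11g to -1.24 (limma adjusted p = 0.0632 and 0.112). Over the 6 runs that left out 1 library, Serpina12 kept its call in 0. Psme1-ps1, Palm3, Fam210a, Kcna2 and Tmprss11g kept theirs in 1 of 6, and Cdkn2b and Skint8 in 2 of 6.

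By list, 8 of 30 epidermal differentiation genes were listed, all 8 lower with lidocaine, and 1, Ivl, passed (1 also when adjusted over the list alone). The others were not past the threshold, with limma adjusted p from 0.0672 to 0.0913. The suprabasal keratin genes Krt1 and Krt10 had log2 differences of -1.81 ± 0.83 and -1.67 ± 0.87 SE and Krt2 of -1.07 ± 0.48. Rptn had a difference of -1.59 ± 0.65, the protease gene Casp14 of -1.30 ± 0.55, and the desmosomal cadherin genes Dsc1 and Dsg1 of -1.44 ± 0.63 and -1.21 ± 0.56. Without lidocaine replicate 2 the differences of Krt1, Krt10 and Casp14 came to -0.97, -0.82 and -0.81. Of the antimicrobial genes 3 were listed, all higher, and 2 passed. These were the neutrophil granule genes Pglyrp1 (from 30.8 ± 8.79 to 83.8 ± 8.65 normalized counts, adjusted p = 0.039) and Camp (from 10.03 ± 1.946 to 30.3 ± 10.7, adjusted p = 0.046). Lcn2 had 3764 ± 1281 and 10248 ± 6257 (adjusted p = 0.069). All 3 passed when adjusted over the list alone, that is over these 3 selected genes of its 20 members. The chemokine genes listed, Ccl5, Ccl7, Ccl12 and Ccl17, and the cytokine list's Il1b, Il6 and Tnfaip6 had higher means with lidocaine, and none passed, over all listed genes or over the list alone. Leaving out 1 library moved Il6 to 0.66 (without lidocaine replicate 2), Lcn2 to 0.86 (without lidocaine replicate 3) and Ccl17 from 1.34 to 0.82 (without imiquimod replicate 2). Il1b had 2813 ± 646 and 6395 ± 2181 normalized counts without and with lidocaine (1.16 ± 0.47 SE, adjusted p = 0.067). Il6 had 377.0 ± 76.0 and 818.7 ± 397 (1.02 ± 0.51 SE, adjusted p = 0.084), and Ccl7 had 9488 ± 1291 and 20179 ± 3182 (1.09 ± 0.44 SE, adjusted p = 0.067).

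Pglyrp1 and Camp kept their calls only without lidocaine replicate 1, with limma adjusted p up to 0.108 and 0.098 in the other runs. The single listed member of a further list was past the threshold in 1 case, the embryonic globin gene Hbe1, which rose from 8.91 ± 4.90 to 43.9 ± 14.6 normalized counts (adjusted p = 0.021), a call lost without imiquimod replicate 1 or 3 or lidocaine replicate 3 (up to 0.0746). Single members not past it were Il22ra1 (-1.43 ± 0.61 SE), Spink5 (-1.08 ± 0.56 SE), Nefh (-1.50 ± 0.70 SE), Serpinb2 (-1.05 ± 0.49 SE), Mmp8 (1.10 ± 0.56 SE) and Tbx21 (1.14 ± 0.53 SE). Without lidocaine replicate 2 Spink5, Nefh and Mmp8 had differences of -0.61, -0.86 and 0.70, and without lidocaine replicate 3 Il22ra1 had -0.85 and Pomc 0.68. The sodium channel gene Scn8a had 35.1 ± 13.5 and 13.9 ± 2.26 normalized counts without and with lidocaine (-1.21 ± 0.48 SE, adjusted p = 0.065). As Il22ra1 and Scn8a are each the only listed member of their list, their p adjusted over the list alone is the unadjusted p, 0.0414 and 0.0315. The neuropeptide list had Npy (1.00 ± 0.52 SE) and Pomc (1.07 ± 0.51 SE), neither past the threshold, and Npy shares its values closely with an overlapping gene model and is uncertain. Il17a, Il17f, Il22, Il23a, S100a8, S100a9, Krt16 and the genes of the hair, interferon and macrophage lists are not in this table. No list had the 5 members past the threshold that the test of direction needed.

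**Figure D2:**
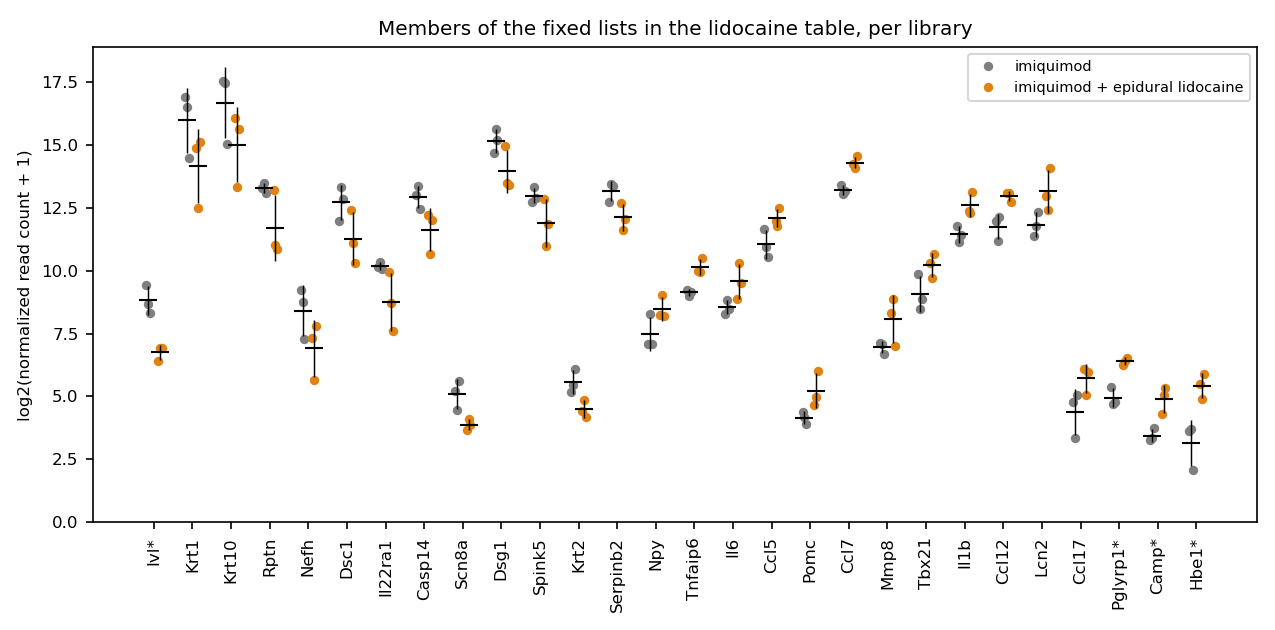
log2(normalized read count + 1) per library for the list members in the lidocaine table, with grey points for imiquimod and orange points for imiquimod with lidocaine, bars for the mean ± SD of 3 samples, and a star for an adjusted p under 0.05. The stars are at Ivl, which was lower, and at Pglyrp1, Camp and Hbe1, which were higher with lidocaine.

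The number of lidocaine calls and their balance changed with the libraries used and with the adjustment. The count of 128, 44 higher and 84 lower, came to 22 (12 higher, 10 lower), 62 (27 and 35) and 58 (24 and 34) without imiquimod replicates 1, 2 and 3. It came to 147 (41 higher, 106 lower), 49 (24 and 25) and 34 (17 and 17) without lidocaine replicates 1, 2 and 3. These runs have fewer samples. Over the 6 runs, 5 of which lost its call, the log2 difference of Pglyrp1 was 1.32 to 1.66, and that of Il1f10, also lost in 5, was -1.74 to -1.39. Of the 35 called genes that are named, Fam71b and P2ry4 stayed past the threshold in all 6 of these runs. As if 23154 genes had been tested, none of the 35 passed (lowest limma adjusted p 0.157). The 2 genes that did were chosen here after their values were seen, the meiosis gene Syce1, at 0 and 16.0 ± 1.48 normalized counts without and with lidocaine, and LOC100360238, at 16.4 ± 3.48 and 0.

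Genes in both tables were used to ask whether lidocaine moved skin back towards the untreated state. Of 227 genes listed in both, 147 moved in the same direction with lidocaine as with imiquimod and 80 (35.2%, exact Clopper-Pearson 95% interval 29.0% to 41.8%, a description across genes) in the opposite one. The largest class held 92 genes lower after imiquimod and lower again with lidocaine. Another 25 of the lowered genes rose with lidocaine. Genes higher after imiquimod split evenly, 55 higher again and 55 lower. Among the 58 genes past the threshold in both, 29 (50%, interval 36.6% to 63.4%) were opposite, 21 higher and then lower and 8 lower and then higher. That share was 100% of 7 genes without imiquimod replicate 1, 85% of 20 without imiquimod replicate 3 and 64.7% of 17 without lidocaine replicate 2. Ivl, Clca5 and Il1f10 were lower at each step, Il1f10 from 2349 ± 654 in untreated skin to 65.6 ± 11.7 with imiquimod and 21.1 ± 5.42 with lidocaine. The same held for the ion channel family gene Ano9 (1203 ± 146, 500.3 ± 73.5 and 170.4 ± 54.7) and Hsd17b2, Slc5a11, Cpvl and Atp8b3. Ptx3, Gabrd and Hbe1 were higher at each step. Slc5a9, a sugar transporter gene, rose with imiquimod from 208.8 ± 74.5 to 823.2 ± 150 and fell with lidocaine to 261.5 ± 142 normalized counts, and Kcna2 went from 66.3 ± 42.8 to 291.9 ± 185 and 67.7 ± 50.3. Sh3gl2 followed the same course, as did P2ry4, Adam28, Npy4r, Lctl and Trim80 at means under 20 counts in each group. Ephx2 fell with imiquimod from 512.7 ± 372 to 47.6 ± 20.9 and rose with lidocaine to 235.5 ± 109. Fam71b, Prr35, Slc22a20, Nmnat2, Drd4 and a gene model named Rps2 took that course at means under 24 counts, and Rps2 is uncertain because ribosomal protein genes have many copies. The imiquimod call was lost in at least 1 run without a library for Ptx3, Ephx2, Kcna2, Sh3gl2, Drd4, Hsd17b2 and Cpvl (highest limma adjusted p 0.087, for Kcna2 without untreated replicate 1). Of the lidocaine differences, that of Hsd17b2 moved from -3.43 to -2.16 without lidocaine replicate 3 and that of Slc5a11 from -2.64 to -1.71 without imiquimod replicate 1. The imiquimod difference of Drd4 moved from -2.43 to -1.61 without imiquimod replicate 1.

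**Figure D3:**
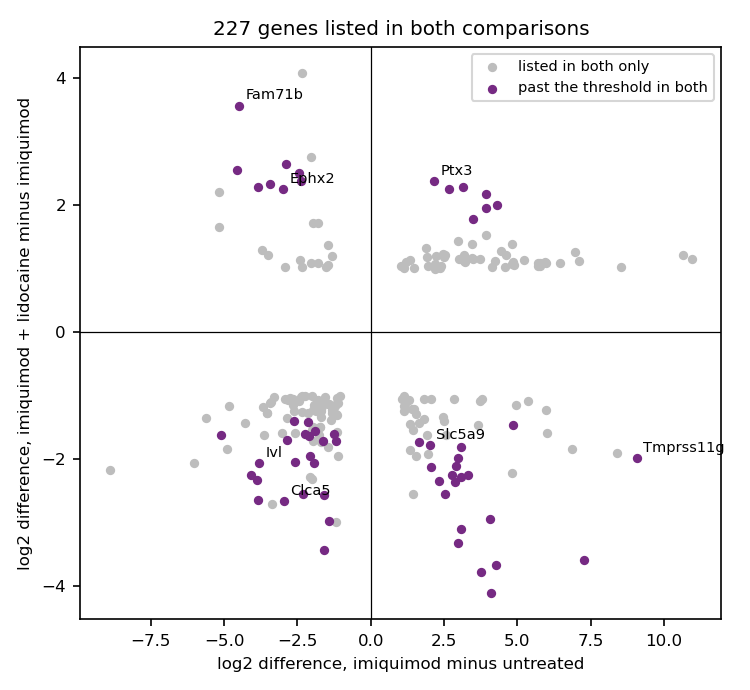
Differences of group means on the log2(normalized count + 1) scale for the 227 genes in both tables, imiquimod minus untreated on the x axis and imiquimod with lidocaine minus imiquimod on the y axis, with purple points for the 58 genes past the threshold in both. The lower left part, lower at each step, holds 92 of the genes.

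The imiquimod libraries stand in both comparisons with opposite sign, so chance alone pushes towards opposite signs. Simulated shares were taken only over genes kept by a difference of 1 and an unadjusted p under 0.05 in both comparisons. With no difference, 1398 of 400000 simulated genes were kept, and 98.8% of these were opposite. With differences for imiquimod as listed and none for lidocaine, 6421 of 400000 were kept, and 64.6% of these were opposite. The listed genes did not all meet this filter, with unadjusted limma p up to 0.573 and 0.219 in the imiquimod and lidocaine tables. Neither share is therefore a like reference for the 227 genes. The overlap of independent lists cannot be computed, since the number of genes tested is not given in the sources used here, and the 3 imiquimod libraries are too few to be split.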

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

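The voom fit, the adjustment over 23154 protein-coding genes and, for genes in both tables, the runs over all listed genes and with 1 library left out were chosen after seeing the data. The direction of every named gene was kept under all alternatives run. Genes listed for a difference of at least 1 between the same libraries can hardly change sign in such runs, so this is no independent check.

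The imiquimod count of 5287 was 3280 at an adjusted p under 0.01 and 244 with Bonferroni, each a stricter threshold by construction, and 4412 to 5408 with 1 library left out. It was 5305 with voom. The lidocaine count of 128 was 13 at an adjusted p under 0.01, 7 with Bonferroni, 25 with a mean of at least 100, 80 with symbols only, 56 with a pseudocount of 0.1, 119 with voom, 2 with the adjustment over protein-coding genes and 22 to 147 with 1 library left out. The excess of lower genes, 84 against 44 higher, was not kept at an adjusted p under 0.01 (5 lower, 8 higher), with Bonferroni (2 and 5), without imiquimod replicate 1 (10 and 12) or without lidocaine replicate 3 (17 and 17). It was 30 against 26 with a pseudocount of 0.1, 25 against 24 without lidocaine replicate 2, and 22 against 3 with a mean of at least 100. The lower counts with a pseudocount of 0.1 were not traced to a cause. Most other settings hold fewer genes, fewer libraries or a stricter threshold. The opposite share of 50% among genes past the threshold in both tables was 100% of 2 genes at an adjusted p under 0.01, 35.2% over all 227 listed genes and 48.2% to 100% with 1 library left out, where as few as 7 genes remained; the cause was not tested. Lists with a split beyond other genes numbered 17, and 10 at an adjusted p under 0.01, where 17 lists were tested. A minimum log2 difference of 1 and a minimum mean of 1 moved nothing.

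As deviations from group means, same-numbered libraries correlated at -0.02, -0.23 and -0.01 in the imiquimod table. In the lidocaine table they correlated at -0.18, -0.09 and -0.06. Differently numbered libraries correlated at -0.23 to 0.25 and at -0.22 to 0.34. With 3 libraries per group, these values cannot show whether samples were paired. With the replicate block 4756 and 92 genes passed. Of the 35 called named genes for lidocaine, 11 lost their call with the block and 24 with a pseudocount of 0.1. Of the 157 for imiquimod, 6 and 1 did.

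Of 157 named genes called for imiquimod, 142 were called with each library left out in turn, and of 35 for lidocaine, 2. Low genes are frequent in the lidocaine table, where 49.1% have a mean under 100 normalized counts. Of its 128 calls, 25 had a mean of at least 100.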

Other observations

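The families and tests in this part were chosen after their values were seen. For the signs of the 227 genes in both tables, the runs without single libraries were added after the tables had arrived, with the decisive share set before their outcome was seen. The families are given as counts, without a test of enrichment. Of 33 listed RT1 genes, the rat major histocompatibility complex, 27 rose and 4 fell past the threshold, with RT1-A2 of class I at 4327 ± 192 normalized counts untreated and 58086 ± 20070 with imiquimod, although reads of this family may be shared between copies. All 8 listed genes of the immunoproteasome and peptide loading rose, Psmb9 by 4.03 ± 0.28 SE and Tap1 by 3.56 ± 0.28 on the log2 scale, as did all 7 granzymes, Gzma by 8.96 ± 1.07 and Gzmk by 9.09 ± 0.78. Of 17 complement gene IDs 14 rose, C3 from 206.3 ± 59.3 to 4206 ± 961. All 29 keratin-associated protein gene IDs fell, and like all listed genes these lists hold only genes the authors had called (55.2% of which were higher).

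With lidocaine, 4 membrane serine protease genes of the Tmprss11 family and 3 Skint genes were listed, all lower, of which Tmprss11g, Skint8 and Skint1 passed the threshold. Tmprss11a and Tmprss11b, which imiquimod had raised by 6.85 ± 0.72 and 8.41 ± 0.77, had differences of -1.83 ± 0.66 and -1.90 ± 0.72 with lidocaine (limma adjusted p = 0.057 and 0.063), which came to -1.18 and -1.21 without lidocaine replicate 3. Tmprss11f, which was lower after imiquimod (-1.69 ± 0.28 SE), had a difference of -1.73 ± 0.63 with lidocaine (limma adjusted p = 0.058). The call of Skint1 was lost in 4 of 6 runs that left out 1 library, imiquimod replicate 1 or 3 or lidocaine replicate 1 or 3 (up to 0.122). Tmprss11g kept its call in 1 and Skint8 in 2 of these 6 runs (limma adjusted p up to 0.112 and 0.095). The metallothionein genes Mt1, Mt1m and Mt2A were listed as higher and none passed, Mt2A with 5825 ± 1906 and 15060 ± 4266 normalized counts (adjusted p = 0.053). The complement gene Cfb had 79466 ± 9581 normalized counts with imiquimod and a log2 difference of 1.03 ± 0.44 SE with lidocaine (adjusted p = 0.07).

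All 8 listed epidermal differentiation genes were lower with lidocaine, with a median log2 difference of -1.52. With each library left out in turn the median was between -1.95 and -1.11. These genes are in the table for a difference between the same libraries, so such runs do not show whether a single library set it. Whether the lidocaine samples held less epidermis cannot be told apart from lower expression, since 22 of the 30 genes of the list are not in the table. An action of the epidural injection itself stays open as well, without a sham-injected group.

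Hair, sebaceous and melanocyte genes were lower after imiquimod. Library scaling, or equal dilution of all skin structures by infiltrating cells, would lower these genes and the fibroblast and matrix genes by the same amount. For the hair genes the values argue against both as the whole cause, since their upper quartile was -5.83 and the quartiles of the fibroblast and matrix genes were -2.40 and -1.30. For the sebaceous genes, with an upper quartile of -1.55, and the melanocyte genes, at -2.49, the ranges overlap or nearly touch, and both explanations stay open. The follicle content or hair phase of the sampled skin cannot be told apart from an effect of imiquimod, because no measure of follicles is among the labels. The hair genes had a median log2 range of 0.96 among the untreated samples and 8.04 among the imiquimod samples.

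Most genes in both tables moved the same way with lidocaine as with imiquimod, an excess found among genes that imiquimod lowered. Of these, 92 fell again and 25 rose, while genes that imiquimod raised split into 55 higher and 55 lower. The shared imiquimod libraries push towards opposite signs, and 35.2% of the 227 genes were opposite. Whether a single library set the signs stays open. The share was at most 35.2% with each library left out, but genes listed for a difference of at least 1 can hardly change sign in such runs. A stronger imiquimod response in the lidocaine group, or an effect of lidocaine, was not tested. Among genes past the threshold in both tables the share was 50%, and 85% and 100% without imiquimod replicates 3 and 1, so this subset does not settle the direction.

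The 6 libraries of each comparison make 10 splits into groups of 3, too few for a share under 0.05. The real split gave 5287 genes for imiquimod and 128 for lidocaine, the highest of the others 0 and 0, and the real one was the 1 split with as many in each comparison, on genes that were selected by that split.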
